A study of Mus musculus with 6 samples.

How the data were processed

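Polyadenylated RNA of 6 mouse samples was made into stranded libraries (TruSeq Stranded mRNA) and sequenced on an Illumina HiSeq 2500, per the labels' protocols and the series design. The deposited files hold read counts per gene, 1 file per sequencing run, and WT replicate 3 has 2 runs, which makes 7 files. The counts have the layout of STAR's gene counter, and STAR 2.5.1b, the genome build GRCm38 and DESeq2 are named per the submitters' processing notes, with no role given for DESeq2. The annotation release behind the counts is not given in the sources used here. Each deposited count is the number of uniquely mapped reads that fell on 1 gene, given without strand, on the strand of the read and on the opposite strand.

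Column 4, the count on the strand opposite to the read, was used because the kit reverses the strand. It held 95.6% to 97.5% of the stranded gene reads in each library. The 4 rows that name no gene (unmapped, multimapping, outside genes and ambiguous reads) were left out of library sizes and tests, and held 25.6%, 28.2% and 47.8% of the reads in WT replicates 1, 2 and 3 and 28.6%, 39.9% and 25.7% in KO replicates 1, 2 and 3. Multimapping reads alone made up 23.0% in WT replicate 3 and 27.0% in KO replicate 2, against 14.4% to 19.2% in the other libraries. Reads that match 2 genes equally well are therefore missing from both genes. The tables list 46983 genes, of which 46488 were matched by identifier to symbols and to GRCm38 coordinates of GENCODE release M21, and 495 were not.

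Samples were grouped by the genotype in their titles. The 2 runs of WT replicate 3 were summed and counted as 1 replicate. They held 27351 and 558 gene reads and differed beyond sampling noise (chi-square over 34 genes, p = 1.5e-169). For example, Slc16a7 had 0 reads in the first run and 25 in the second, so that its high normalised value in WT replicate 3 comes from that run alone. The main test was set before the data were examined. Genes were filtered with filterByExpr, scaled with TMM and tested with edgeR 4.0.16 (glmQLFit with robust estimation, then glmQLFTest, two-sided), with genotype as the only term and a Benjamini-Hochberg adjusted p of 0.05 as the threshold. Standard errors are the log2 fold change divided by the root of the F statistic. Normalised CPM are read counts scaled to the effective library size with edgeR's cpm function. The filter asks for reads in 3 libraries, and a gene read only in WT can hardly meet it with WT replicate 3 as shallow as it is. For the same reason a gene without reads in WT replicate 3 cannot be lower in KO with no overlap between the groups.

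The 29 gene lists covered blood lineages, other cell types the cultures could hold, HOX and MLL-fusion targets, partners of LEDGF, cell cycle, repair, stress, metabolism and sex-linked markers. Lists with at least 5 tested members, other than the sex-linked one, were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation. Fry was run beside it. The neighbourhood of Psip1 was tested by camera and by Fisher's exact test. The sex-linked list had 4 tested members, whose reads followed the libraries and not the genotype.

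The genes named in the text follow a rule set before the data were examined. Psip1, Hdgfl2, Hdgf, Men1, Kmt2a, Hoxa9, Hoxa10 and Meis1 were always named. Among genes past the threshold, with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a clone or predicted name, the 10 of largest change per direction would have followed. As no gene passed, the 5 genes of lowest p per direction under the same filters were named, and for each called list its 3 members of lowest p, except for 1 member that is not reported here. Ctse, Gm9025, Ifi202b, Peg3, Peg12, Hoxa5, Hoxa7, Eya1, Mpo, Cpa3, Hdc, Kit, Cd74, Ctsk, C1qa, F13a1, Elavl2, Xist, Eif2s3y, Slc16a7 and all genes that only the closing part names were chosen after their values were seen.

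The test was checked on simulated counts drawn from the means, dispersions and library sizes of these 6 libraries, with 50 genes changed at each of 4 sizes. In a further simulation 24 of the calls were false beside 144 true ones (14.3%) with all 6 libraries, against 14 beside 143 (8.9%) with edgeR's adjusted deviances and 12 beside 130 (8.5%) without WT replicate 3. All of these lie above the nominal 5%. The list test called the 1 shifted list and 0 of the unshifted ones. Its genes were simulated independently and its lists drawn at random. It therefore cannot show how the preset correlation of 0.01 performs where members move together. The estimated correlation of the dendritic cell list, for example, was 0.63. Alternatives covered scaling, filtering, DESeq2 1.42.0, limma-voom, counts without strand, single runs of WT replicate 3, the replicate number as a block, leaving out each library, and thresholds. Alternatives added after the data were seen were a filter of at least 10 reads in 2 libraries, edgeR's adjusted deviances, Y-linked reads as a covariate, leaving out both libraries with a high mitochondrial share, and DESeq2 or the other filter without WT replicate 3. R 4.3.3, Python 3.11.15, SciPy 1.17.1 and Matplotlib 3.10.9 were used.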

Results

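Messenger RNA was sequenced from colonies that bone marrow progenitors formed in culture. Lineage-depleted cells, which are marrow cells stripped of mature blood cells, came from C57BL/6 mice and grew in methylcellulose with IL-3, IL-6 and stem cell factor. Colonies were harvested after 6 to 7 days. The 6 samples formed 2 groups of 3. The first group, WT, is named wild type in the labels, while the series design describes its mice as homozygous for a floxed Psip1 allele. The second group, KO, is named Psip1 knockout, and the design marks its allele with the name Vav. Psip1 encodes LEDGF, a chromatin-bound protein that tethers the MLL and menin complex to active genes. The series title places the comparison in the question of whether this protein is needed in normal blood formation, as opposed to leukaemia driven by MLL fusions.

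Depth was uneven. WT replicates 1 and 2 held 14332364 and 10418101 reads on genes, and KO replicates 1, 2 and 3 held 12714022, 7056614 and 15569088. WT replicate 3 held 27909 gene reads over its 2 sequencing runs, so that the shallowest of the other libraries was 253 times deeper. In that library 1 read was worth 29.9 normalised CPM, the read count scaled to the effective library size, and a count of 0 allows up to 89.6 CPM, which is the level of 3 reads. Values of WT replicate 3 are therefore given as reads. Mitochondrial genes took 1.52%, 1.26% and 9.52% of gene reads in WT replicates 1, 2 and 3 and 1.84%, 15.74% and 1.57% in KO replicates 1, 2 and 3 (95% Wilson interval of WT replicate 3, 9.18% to 9.87%). Intervals and floors cover counting error only. The labels do not say whether the libraries of a group came from separate animals. Xist had 5910 reads in WT replicate 2 and 12107 in KO replicate 1, where the Y-linked Eif2s3y had 0. WT replicate 1 and KO replicates 2 and 3 had 1078, 865 and 1144 Eif2s3y reads. Each group thus held libraries from more than 1 animal, though not all need be separate. P-values measure the spread between these libraries, which may in part be technical.

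Psip1 (ENSMUSG00000028484.16, minus strand of chromosome 4, 83455680 to 83486459, GRCm38) was lower in each KO library than in each WT library. WT replicates 1 and 2 stood at 89.3 and 70.0 CPM, and the KO libraries at 14.8, 17.6 and 16.3 CPM, a mean of 16.2 ± 1.39 (SD, n = 3). WT replicate 3 held 3 Psip1 reads, with an exact 95% interval of 0.619 to 8.77 reads, where the KO mean would give 0.543. The labels and the Psip1 level therefore went together in all 5 deep libraries, and in WT replicate 3 the interval lay above the KO mean, on 3 reads. The fitted difference was a log2 fold change of -2.32 (SE 0.32), or 4.98-fold lower, and KO libraries held 19.5% of the WT level. The quasi-likelihood test of edgeR gave an adjusted p = 0.0599 after Benjamini-Hochberg adjustment over 12292 genes, which misses the threshold of 0.05. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 libraries against 3 can reach. The count covers the whole gene, so it also holds reads from outside any deleted exon. Of 24 alternatives 5 called Psip1 lower, with log2 fold changes from -2.45 to -2.07 and adjusted p from 7.81e-08 to 1.

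**Figure D1:**
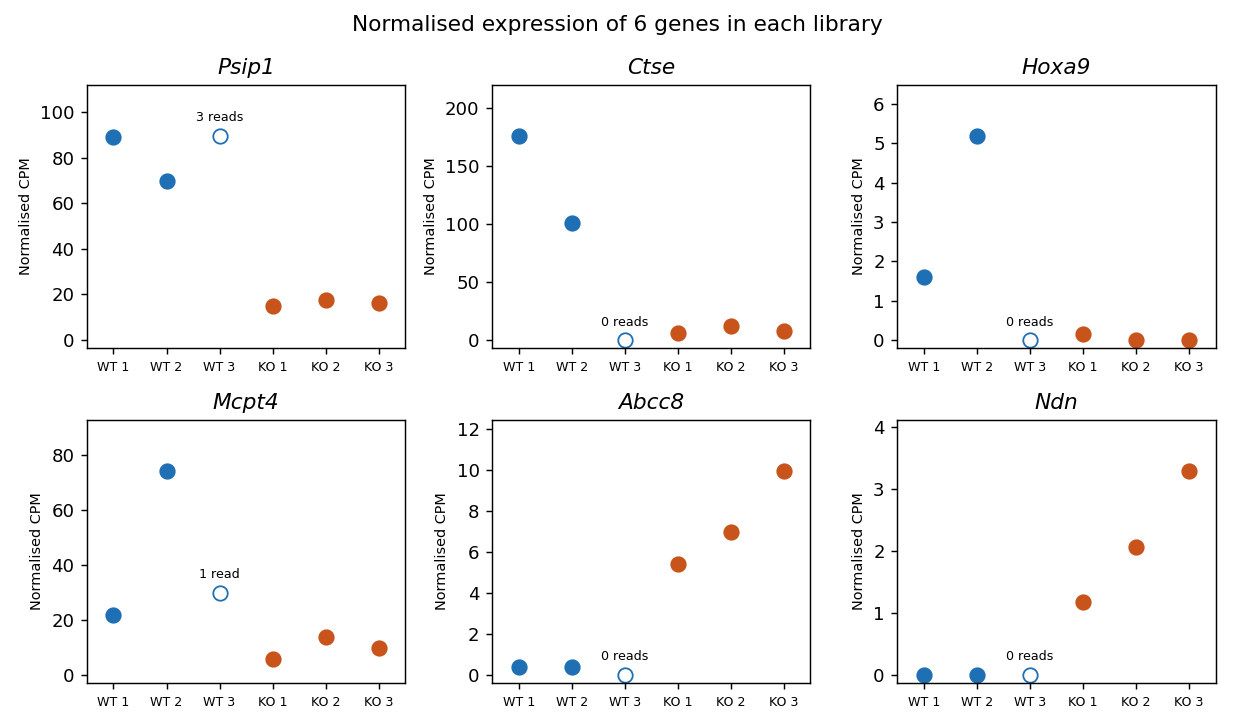
Normalised CPM of 6 genes (vertical axes, linear scale) in each of the 6 libraries (horizontal axes), with WT in blue, KO in orange, 1 point per library and an open circle with its number of reads for WT replicate 3. The KO libraries stood at 14.8 to 17.6 CPM for Psip1 and at 6.21 to 11.9 CPM for Ctse, below the deep WT libraries, while Abcc8 and Ndn lay higher in each KO library than in both deep WT libraries.

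No gene passed the threshold between the genotypes. The 4 genes closest to it, with adjusted p under 0.1 by edgeR's quasi-likelihood test, were Gm9025, Ctse and Psip1 on the lower side and Abcc8 on the higher side. Ctse, which encodes the aspartic protease cathepsin E (chromosome 1, 131638306 to 131675505), stood at 175.5 and 100.9 CPM in WT replicates 1 and 2 and at 6.21, 11.9 and 7.39 CPM in the KO libraries (log2 fold change -3.84, SE 0.53, adjusted p = 0.0599). Gm9025, a processed pseudogene on chromosome 13, held 222 and 130 reads in the same WT libraries and 10, 7 and 11 in KO (log2 fold change -3.99, SE 0.52, adjusted p = 0.0599). As a processed pseudogene can share reads with the gene it derives from, its count is uncertain. Ctse and Gm9025 were named after their values were seen, and both had 0 reads in WT replicate 3. For Ctse that 0 allows up to 89.6 CPM by counting error alone, so the lower level in KO rests on the 2 deep WT libraries. Abcc8, the sulfonylurea receptor of potassium channels, had 5 and 4 reads in the deep WT libraries and 69, 44 and 151 in KO (log2 fold change 4.27, SE 0.62, adjusted p = 0.0644).

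Beyond these, the genes with the lowest p on the higher side were scarce transcripts. Fzd8, a Wnt receptor, had 1 and 2 reads in the deep WT libraries and 26, 14 and 33 in KO (adjusted p = 0.266). Ndn, an imprinted gene that encodes necdin, had 0 reads in every WT library and 15, 13 and 50 in KO, at least 18.3-fold higher against a floor of 3 reads over the group. Uchl1, a neuronal deubiquitinase, went from 5 and 3 reads to 39, 44 and 56, and Adamts1, a secreted metalloprotease, from 8 and 6 to 66, 23 and 84. On the lower side stood Mcpt4, a mast cell chymase (21.6 and 74.4 CPM in the deep WT libraries, 9.63 ± 4.01 in KO, SD, n = 3), Hnmt, which inactivates histamine (log2 fold change -1.39, SE 0.47), the replication factor gene Pclaf (-0.94, SE 0.33) and the transcription factor gene Mef2c (-1.05, SE 0.37). All were far from the threshold, with adjusted p of 0.266 or more.

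Of the 12292 genes, 178 had an unadjusted p under 0.05, of which 152 were higher and 26 lower in KO, where chance alone would give 615. The filter can keep genes read only in KO but hardly those read only in WT, so the 2 directions are not on an equal footing. Without a low-count filter edgeR had 408 higher and 165 lower, and without WT replicate 3 it had 107 and 31. At the same level DESeq2 had 16 higher and 22 lower and limma-voom 78 and 30. The DESeq2 test ran on 22213 genes with a median log2 fold change of -0.32, and without WT replicate 3 it had 178 higher and 44 lower. DESeq2 called 1 gene, Ctse, lower, and limma-voom called 0. In simulated data with the dispersions and depths of these libraries, the test called 10% of the genes changed by 1 log2 unit. For changes of 2, 3 and 4 units it called 80%, 98% and 100%. These were 50 genes at each size, changed together and drawn only from genes above a minimum level. Where fewer genes change, the adjusted threshold is harder to reach, so these shares may not hold for the data. There Ctse, Gm9025 and Abcc8 missed the threshold at log2 fold changes of -3.84, -3.99 and 4.27. The number of genes called moved with the libraries used. With WT replicate 3 left out, edgeR called 0 genes and DESeq2 called 12 (7 higher and 5 lower), among them Psip1, Ctse, Hoxa9, Abcc8 and Adamts1, a setting added after the data were seen. Without WT replicate 1 or KO replicate 3 edgeR called 5 genes each time, without WT replicate 2 it called 3 and without KO replicate 1 it called 2.

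The HOXA cluster, whose 5' genes are the best known targets of MLL fusions, was close to silent in these colonies, and the reads that remained lay mainly in WT. Hoxa9 (chromosome 6, 52223100 to 52231089) held 22 and 53 reads in WT replicates 1 and 2 against 2, 0 and 0 in KO, a WT to KO ratio of 53.4 with an exact counting interval of 14.3 to 449. Hoxa7, named after its values were seen, held 16 and 20 reads against 0, 0 and 4. Hoxa10 held no more than 1 read in any library. Of the 12 members of this list only Meis1, a HOX cofactor, had enough reads to be tested, and its log2 fold change was -0.23 (SE 0.52). Hoxa9 was left out of the main test because the filter asks for reads in 3 libraries. In the 10 alternatives that tested it, 2 called it, with adjusted p from 0.00425 without a filter to 1 in several.

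Other genes that MLL fusions activate lay mostly on the lower side in KO. Of 14 tested, 11 had a negative and 3 a positive log2 fold change, with a median of -0.15, and 0 passed the threshold, adjusted over all genes or adjusted over the list alone. The transcription factor gene Mef2c was at -1.05 (SE 0.37), while Bcl2, which blocks apoptosis, was at 0.40 (SE 0.52). Eya1, a transcriptional coactivator gene that was too scarce to test and was named after its values were seen, held 36 and 8 reads in WT replicates 1 and 2 and 1, 0 and 3 in KO. Camera with a preset correlation called this list lower (adjusted p = 0.0407), and with an estimated correlation the adjusted p = 0.841. Leaving out any 1 of 4 libraries (WT replicate 1 or any KO library) ended that call, with adjusted p from 0.0714 to 0.775.

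None of the partners and paralogs of LEDGF passed the test in either direction. Among 14 tested members the median log2 fold change was 0.04, and by edgeR 0 passed the threshold, over all genes or adjusted over the list alone. The closest relative, Hdgfl2, was at 0.00 (SE 0.38), and Hdgf was at -0.47 (SE 0.44). Men1, which encodes menin, was at -0.24 (SE 0.34), and Kmt2a, which encodes MLL, was at 0.35 (SE 0.44). Several of these signs turned. Hdgfl2 was at -0.07 with scaling by library size only, at -0.26 without WT replicate 1 and at -0.24 without KO replicate 2. Men1 was at 0.10 without WT replicate 2, and Hdgf at 0.09 with the second run of WT replicate 3 alone.

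The colonies were myeloid in both genotypes, and markers of neutrophils and mast cells differed widely between libraries of 1 genotype. Mpo, the myeloperoxidase of primary neutrophil granules, stood at 720 and 3036 CPM in WT replicates 1 and 2 and at 2774, 843 and 558.6 in KO replicates 1, 2 and 3. Cpa3, the carboxypeptidase of mast cells, ran the other way, at 2488 and 854.3 CPM in WT and 1156, 3453 and 2606 in KO. WT replicate 1 was closest to KO replicate 3 (Spearman correlation 0.991 across genes) and WT replicate 2 to KO replicate 1 (0.985), above the 0.926 between WT replicates 1 and 2. Genes are not independent replicates, and these correlations describe the libraries only. Xist was read in WT replicate 2 and KO replicate 1 (5910 and 12107 reads), while the Y-linked Eif2s3y was read in the other 4 libraries. Among the 6 libraries the first component, 97% of the variance of 500 genes, set WT replicate 3 apart, and among the 5 deep ones the first held 58.4%.

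**Figure D2:**
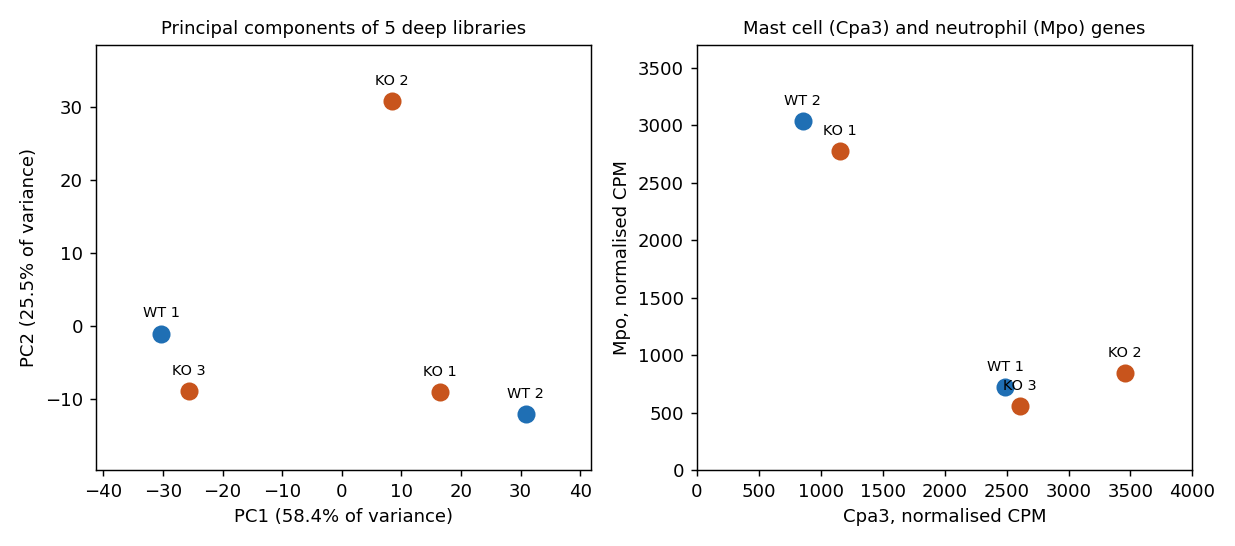
Left, the first and second principal components of log2 CPM of the 500 most variable genes in the 5 deep libraries; right, normalised CPM of Cpa3 (horizontal axis) against Mpo (vertical axis) in the same libraries, both axes linear. WT is blue, KO is orange and each point is 1 library. WT replicate 2 and KO replicate 1, at 3036 and 2774 CPM of Mpo, lay apart from the other 3 libraries, at 558.6 to 843 CPM.

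Of the 29 gene lists fixed before the data were examined, 26 had at least 5 tested members and were compared by camera, and 12 were called, 11 of them lower and 1 higher in KO. No call held with an estimated correlation, where the adjusted p of these 12 lists ran from 0.841 to 0.865, and fry, which asks whether a list moves on balance one way, gave 0.919. Every one of the 12 also lost its call when at least 1 library was left out. Across all 29 lists, 1 member passed the threshold adjusted over the list alone (Mcpt4), and 0 did over all genes.

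Primary neutrophil granule genes leaned lower in KO. Of 12 tested members 10 had a negative log2 fold change, with a median of -0.54 (camera adjusted p = 0.000271, and adjusted p = 0.841 with an estimated correlation). The lowest p belonged to Nkg7, a granule membrane gene (-1.30, SE 0.82), Cebpe, a transcription factor of granulocytes (-0.67, SE 0.49), and Ms4a3 (-0.60, SE 0.52). Leaving out WT replicate 2 or KO replicate 2, the library with 15.74% mitochondrial reads, ended this call (adjusted p = 0.63 and 0.152). Secondary and tertiary granule genes (19 tested, median -0.17, camera adjusted p = 0.163) and genes of mature neutrophils (19 tested, median 0.18, adjusted p = 0.93) were not called.

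Mast cell and basophil genes split. The chymases Mcpt4, Mcpt1 and Mcpt2 had log2 fold changes of -2.28 (SE 0.53), -2.53 (SE 0.74) and -1.92 (SE 0.75), and Mcpt4 was the 1 gene that passed adjusted over the list alone (adjusted p = 0.0252 by edgeR), lower in KO. Cpa3 (0.75, SE 0.56), Hdc (0.70, SE 0.48) and Kit (0.01, SE 0.52) did not follow. Of 23 tested members 12 had a positive and 11 a negative value. The median was 0.01 and the mean -0.22, so that camera's call of this list as lower (adjusted p = 0.0461, and adjusted p = 0.865 with an estimated correlation) had the sign of the mean and not of the median. DESeq2 turned the direction (adjusted p = 0.227), as did leaving out KO replicate 1 (0.723), and leaving out WT replicate 1 or 2 or KO replicate 3 ended the call (0.817, 0.157 and 0.268).

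Antigen presentation genes of dendritic cells were the 1 list called higher. All 11 tested members had a positive log2 fold change, with a median of 0.46 (camera adjusted p = 0.00259, and adjusted p = 0.846 with an estimated correlation). Itgax, which encodes CD11c, was at 0.97 (SE 0.46), Clec9a, a marker of cross-presenting dendritic cells, at 1.73 (SE 0.88) and the class II gene H2-Aa at 0.65 (SE 0.37), while Cd74, the invariant chain, was at 0.04 (SE 0.36). H2-Aa stood at 125.9 CPM in KO replicate 2 and at 86.1 and 71.8 in the other KO libraries. Without KO replicate 2 the list's adjusted p was 0.709, and without WT replicate 1 it was 0.705.

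Monocyte and macrophage genes were not called as a list (27 tested, median 0.18, mean -0.09, camera adjusted p = 0.946), yet members lay on both sides. The protease gene Ctsk was at 1.33 (SE 0.37), and the complement gene C1qa and the coagulation factor gene F13a1 were at -2.35 (SE 0.67) and -1.42 (SE 0.43). Each had 0.0585 when adjusted over the list alone by edgeR, just outside the threshold. Eosinophil genes (9 tested, median 0.11, adjusted p = 0.128), megakaryocyte genes (18 tested, median -0.06, mean 0.05, adjusted p = 0.93) and stem and progenitor genes (17 tested, median 0.01, adjusted p = 0.93) were not called.

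Erythroid genes were scarce and leaned lower. Of 12 tested members 11 had a negative value, with a median of -0.48 (camera adjusted p = 0.000507, and adjusted p = 0.841 with an estimated correlation). Hbb-bt, a beta globin that shares reads with its close copy Hbb-bs, was at -1.14 (SE 0.92), and the carbonic anhydrases Car2 and Car1 were at -0.71 (SE 0.60) and -1.09 (SE 0.97). The call was lost without WT replicate 2 (adjusted p = 0.63) or without KO replicate 3 (adjusted p = 0.347). The T and NK cell list was called lower on 5 tested members (camera adjusted p = 0.0461, and adjusted p = 0.841 with an estimated correlation). Its members of lowest p were Nkg7, which is also on the granule list, Cd247, a T cell receptor subunit (-1.46, SE 1.64), and Gzmb, a granzyme (-0.30, SE 0.41), and leaving out any 1 library ended the call. B cell genes had 4 tested members, with a median of -0.22, and stromal and endothelial genes had 5, with a median of 0.29 (camera adjusted p = 0.821).

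Genes of proliferation lay slightly lower in KO. In S phase 22 of 24 and in mitosis 23 of 27 tested members had a negative log2 fold change, with medians of -0.17 and -0.22 (camera adjusted p = 0.00259 for each, and adjusted p = 0.855 for each with an estimated correlation). The helicase gene Mcm7, the ribonucleotide reductase gene Rrm1 and Cdc45 were at -0.58 (SE 0.44), -0.46 (SE 0.37) and -0.46 (SE 0.37), and the spindle genes Nusap1 and Ckap2l and the cyclin gene Ccna2 were at -0.46 (SE 0.32), -0.45 (SE 0.35) and -0.33 (SE 0.33). Homologous recombination and repair genes had a median of -0.15 (21 of 23 negative, adjusted p = 0.0343, and adjusted p = 0.855 with an estimated correlation), with Nbn at -0.48 (SE 0.34), Rad54b at -0.32 (SE 0.40) and Fanca at 0.35 (SE 0.39). LEDGF has a known part in this repair pathway. Without KO replicate 2, the library of high mitochondrial share, none of these 3 lists was called (adjusted p = 0.325, 0.642 and 0.642), and without WT replicate 2 none was either (0.63 with the S phase list turned in direction, 0.789 and 0.28). Leaving out WT replicate 1 ended the calls of mitosis and repair (0.0919 and 0.256), leaving out KO replicate 3 ended that of repair (0.0643), and with DESeq2 none of the 3 was called (0.966, 0.984 and 0.261, the last turned in direction).

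Metabolic genes leaned the same way. All 20 tested genes of cholesterol biosynthesis had a negative value, with a median of -0.32 (camera adjusted p = 1.7e-06, and adjusted p = 0.841 with an estimated correlation). Cyp51 and Mvd, enzymes of the pathway, were at -0.70 (SE 0.40) and -0.56 (SE 0.36), and Stard4, a sterol carrier, was at -0.56 (SE 0.35). Of 21 glycolysis and hypoxia genes 16 were negative, with a median of -0.30 (adjusted p = 0.00222, and adjusted p = 0.846 with an estimated correlation), and the hypoxia targets Egln3, Ankrd37 and Pdk1 were at -1.06 (SE 0.42), -0.95 (SE 0.47) and -0.63 (SE 0.42). Genes of the unfolded protein and amino acid response had a median of -0.14 (14 of 20 negative, adjusted p = 0.0461, and adjusted p = 0.841 with an estimated correlation), with Chac1 at -0.57 (SE 0.46), Sdf2l1 at -0.31 (SE 0.32) and Herpud1 at -0.29 (SE 0.33). Leaving out WT replicate 1 or KO replicate 2 ended the cholesterol call (adjusted p = 0.174 and 0.0714), leaving out WT replicate 2 turned the glycolysis list (adjusted p = 0.908), and leaving out any 1 library ended the third.

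The remaining lists were not called by camera. These were p53 targets (20 tested, median 0.02, adjusted p = 0.946), interferon-stimulated genes (24 tested, median -0.04, adjusted p = 0.821), inflammatory genes (21 tested, median -0.13, adjusted p = 0.946), immediate early genes (20 tested, median 0.15, adjusted p = 0.946), heat shock genes (16 tested, median 0.05, adjusted p = 0.71), Myc and nucleolar genes (24 tested, median 0.01, adjusted p = 0.93) and the partners of LEDGF (adjusted p = 0.821). With DESeq2, whose median over all genes was -0.32, 13 of 28 lists were called, 11 higher and 2 lower in KO, and only the call of dendritic cells was shared with edgeR (adjusted p = 0.00737). The 2 lower lists, with too few tested members in edgeR, were the HOXA cluster with Meis1 (0.00471) and B cells (0.0394). The other 10 higher lists were p53 targets (0.017), inflammatory genes (0.0208), Myc genes (0.00638), megakaryocytes (0.0201), monocytes and macrophages (0.00147), mature neutrophils (0.00147), eosinophils (0.00332), immediate early genes (0.00737), heat shock genes (0.0208) and the partners of LEDGF (0.0394). The inflammatory list was also called higher without WT replicate 1 or KO replicate 1 (adjusted p = 0.00632 and 0.00151) and lower without WT replicate 2 or KO replicate 3 (0.00084 and 0.0444). For the p53, Myc and stem cell lists camera's direction was lower although median and mean were at or above 0, and for monocytes and megakaryocytes the median and mean differed in sign.

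**Figure D3:**
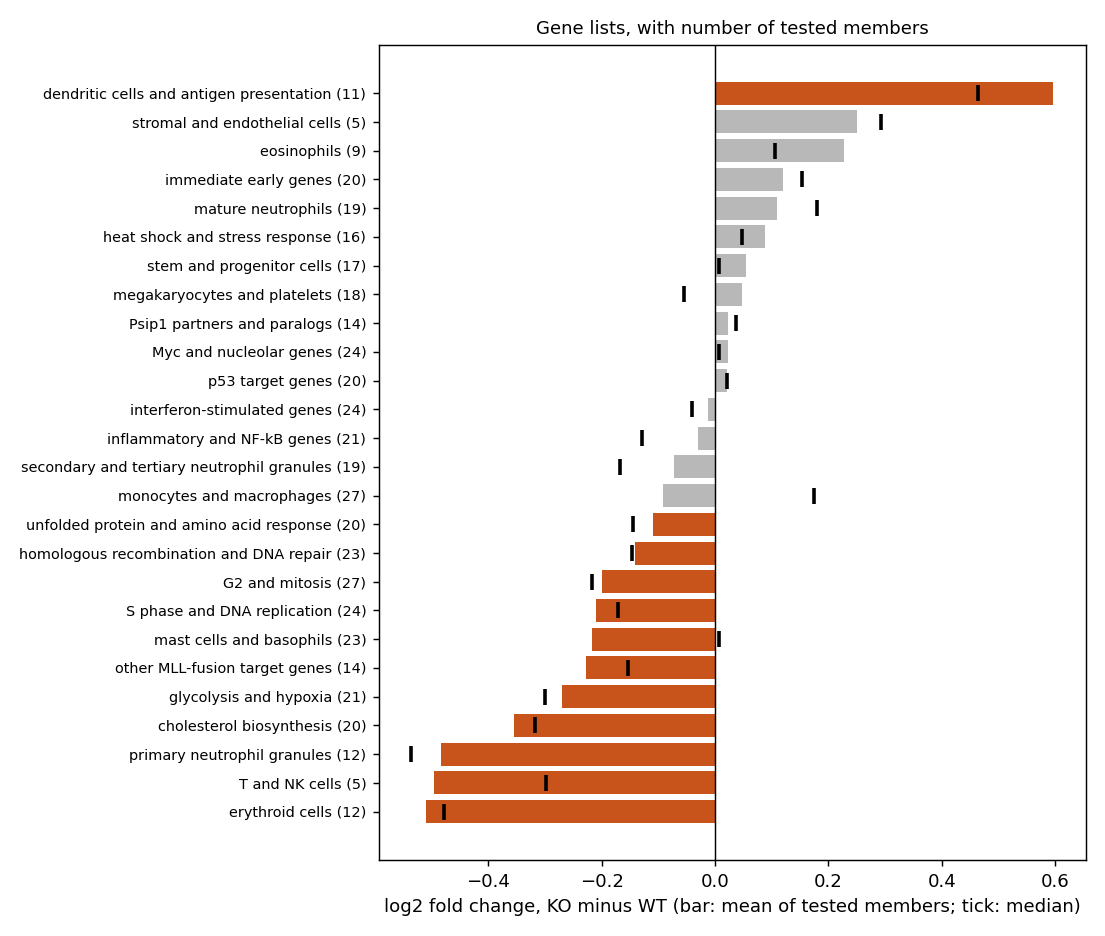
Mean (bars) and median (black ticks) log2 fold change, KO minus WT, of the tested members of 26 gene lists, with the number of tested members in brackets. Orange bars are the 12 lists called by camera with a preset correlation, which range from erythroid genes at a mean of -0.51 to dendritic cell genes at 0.60, and grey bars were not called.

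The neighbourhood of Psip1 on chromosome 4 was examined because a targeted allele can carry flanking sequence from another strain. The series design describes the WT mice as homozygous for a floxed Psip1 allele, so both groups may carry the same flanks. In that case no difference from flanking sequence would be expected. Of 24 tested genes within 10 Mb, 2 had an unadjusted p under 0.05, or 8.3% against 1.4% elsewhere (Fisher's exact test, two-sided, odds ratio 6.24, p = 0.0467). Elavl2, which encodes a neuronal RNA-binding protein (91250763 to 91400785), held 10 and 29 reads in WT replicates 1 and 2 and 411, 19 and 338 in KO. By the same exact test within 20 Mb, 4 of 66 genes did so (6.1% against 1.4%, odds ratio 4.47, p = 0.0153), and within 5 Mb 0 of 16. The median log2 fold change within 10 Mb was 0.18, and camera called the neighbourhood higher with an unadjusted p of 0.019. The camera call was lost within 5 Mb (16 genes, camera p of 0.513) and within 20 Mb (66 genes, 0.568), without WT replicate 2 (0.618), WT replicate 3 (0.0531) or KO replicate 3 (0.112), and with limma-voom (0.0659), and DESeq2 turned its direction (0.621).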

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

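The Y-linked covariate, the other filter, the fit on 2 against 2 libraries and both fits that pair another choice with leaving out WT replicate 3 were chosen after the data were seen. Where a value moved, the cause was not tested. The number of genes called, 0 by edgeR (178 at an unadjusted p under 0.05), became 2 (0 higher, 2 lower) with library size only, 9 (4 and 5) without a low-count filter, 1 (0 and 1) with DESeq2, 13 (10 and 3) with the second run of WT replicate 3 alone, 4 (1 and 3) at an adjusted p under 0.1, 4 (1 and 3) with the Y-linked covariate and 12 (7 and 5) with DESeq2 without WT replicate 3. Leaving out 1 library gave 0 to 5 genes (0 to 2 higher, 0 to 5 lower). Expression gave no sign that the same replicate numbers pair the samples, as deviations of same-numbered libraries correlated at -0.287, -0.032 and -0.146 across genes. These deviations are from group means, so the WT ones carry the counting noise of WT replicate 3. A pairing in how the samples were handled cannot be told from them. The fit with the replicate number as a replicate block called 13 genes (8 higher and 5 lower) and put Psip1 at -2.33 (adjusted p = 0.048). Psip1 was lower in all 24 alternatives and passed the threshold in 5, the others being no filter (-2.29), the second run (-2.25), the Y-linked covariate (-2.34) and DESeq2 without WT replicate 3 (-2.32), and leaving out 1 library gave -2.45 to -2.12. The 12 lists called became 0 with an estimated correlation, 0 with fry, 7 with 2 against 2 libraries and 3 to 12 with 1 library left out. DESeq2, under which the median log2 fold change of all genes moved to -0.32, turned the direction of the lists of mast cells (adjusted p = 0.227), homologous recombination (0.261) and the unfolded protein response (0.221), and those of megakaryocytes (0.0201), p53 targets (0.017), inflammatory genes (0.0208) and Myc (0.00638) turned and were called higher, so that 1 of its 13 calls (11 higher, 2 lower) was shared. With 1 library left out, adjusted p values signed by direction (negative for lower in KO) ran from -0.817 to 0.723 for mast cells, turned without KO replicate 1, from -0.325 to 0.63 for S phase and from -0.0213 to 0.908 for glycolysis, both turned without WT replicate 2, and from -0.94 to 0.00632 for inflammatory genes, called higher without WT replicate 1 or KO replicate 1 (0.00151) and lower without WT replicate 2 (-0.00084) or KO replicate 3 (-0.0444). The neighbourhood of Psip1 (camera p of 0.019) had a p of 0.2 without a filter, 0.621 in the other direction with DESeq2, 0.0659 with limma-voom, 0.188 with the second run, 0.513 within 5 Mb, 0.568 within 20 Mb, 0.0577 with the Y-linked covariate, 0.0892 with the other filter without WT replicate 3, and 0.00484 to 0.618 with 1 library left out. Named genes had 1173 alternative values, of which 1133 stayed on their side of the threshold, 40 passed it and 18 changed sign. Depth limits what WT replicate 3 can show, as 1 of its reads is worth 29.9 CPM.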

Other observations

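All tests of explanations in this part were chosen after the result was seen, and the counts of splits were planned. The genes of this paragraph and the next were chosen after their values were seen, and form no fixed list. Each of Marco, Mmp12, Ccnd1, Fgfr1 and Meis3 stood higher in each KO library than in both deep WT libraries, and none passed the threshold with all 6 libraries in edgeR as set beforehand. Marco, a scavenger receptor of macrophages, was at 3.85 and 3.43 CPM in WT replicates 1 and 2 and at 10.6, 14.9 and 15.1 CPM in KO (log2 fold change 1.91, SE 0.44). Mmp12, the macrophage elastase, was at 1.03 (SE 0.49), but its 33 reads in WT replicate 3, or 985.7 CPM, lay above the 847.7 CPM of KO replicate 3. Ccnd1, which encodes cyclin D1, was at 1.80 (SE 0.45), the growth factor receptor gene Fgfr1 at 2.02 (SE 0.55), and the homeobox gene Meis3 at 2.22 (SE 0.61). For Ccnd1 and Fgfr1 too, WT replicate 3, with 1 and 2 reads (29.9 and 59.7 CPM), lay above KO replicate 1 (19.2 and 38.9 CPM). With the second run of WT replicate 3 alone, which held 558 gene reads and was 89.58% unmapped, edgeR called Ccnd1 (adjusted p = 0.0267) and Fgfr1 (adjusted p = 0.0351). DESeq2 without WT replicate 3 called Marco (adjusted p = 0.0292) and Ccnd1 (adjusted p = 0.024).

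Peg3, Peg12 and Mest are imprinted genes expressed from the paternal allele. Peg3 held 0 reads in every WT library and 13, 10 and 39 in KO, at least 14.5-fold higher against a floor of 3 reads over the group. Peg12 was at 2.32 and 3.92 CPM in the deep WT libraries and at 10.3, 10.8 and 7.32 in KO (log2 fold change 1.62, SE 0.49). Mest held 2 and 2 reads in WT replicates 1 and 2 and 26, 6 and 9 in KO.

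WT replicate 1 was most like KO replicate 3, and WT replicate 2 most like KO replicate 1. A swap of labels between the genotypes is argued against by Psip1, whose lowest deep WT level was 3.99 times the highest KO level. RNA quality stays open, since the mitochondrial shares overlapped between the like pairs (gap -0.31 percentage points), while the other 4 of the 5 measures compared, such as multimapping reads (14.4% and 15.0% against 19.2% and 17.7%), set the pairs apart. Sex of the animals stays open too. Of 10 splits of the deep libraries 3, the split by Y-linked reads included, gave a difference in correlation as large as that split, the highest other being 0.0326. With 10 splits no share under 0.05 can be reached, and this split sets WT replicate 2 and KO replicate 1 apart. The test therefore cannot decide. RNA quality or sex may account for the pairs, as may the makeup of the colonies, which was not tested apart from them.

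Ctse, Gm9025 and Ifi202b were lower in KO than in both deep WT libraries, all had 0 reads in WT replicate 3, and for Ctse, at 175.5 and 100.9 CPM in the deep WT libraries, that 0 allows up to 89.6 CPM by counting error alone. Ifi202b, an interferon-inducible gene on chromosome 1 (173962568 to 173982744), held 112 and 36 reads in WT replicates 1 and 2 and 0 in each KO library, at least 70.2-fold lower. A chromosome 1 segment that differs between the genotypes may account for Ctse and Ifi202b, while Gm9025, whose count is uncertain because of shared reads, lies on chromosome 13. Between Ctse and Ifi202b, 8 of 231 other genes had an unadjusted p under 0.05 against 169 of 12059 elsewhere (odds ratio 2.52, 95% interval 1.06 to 5.17, Fisher's exact test p = 0.0187). Neighbouring genes are not independent, 7 of 364 windows of that length on other chromosomes held as high a share, and 6 of the 8 genes were higher in KO.

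Ndn, Peg3, Abcc8, Fzd8 and Uchl1 had few or no reads in WT and reads in each KO library. Lower depth of WT replicates 1 and 2 is argued against by their 14332364 and 10418101 gene reads, within the 7056614 to 15569088 of the KO libraries. The lowest KO levels of the 5 genes would give 306 reads in these WT libraries, where 20 were found. As the genes were picked for few WT reads, a shortfall of this kind was built in. Stromal cells in the KO cultures stay open, since Col3a1, Dcn, Lum and Cxcl12 had 0 reads in KO, where Ndn had 78, while Pdgfra, Cdh5 and Cdh2 of the 13 other stromal and endothelial genes were higher in each KO library than in both deep WT libraries. A chromosome 7 segment could bear on Ndn, Peg3 and Abcc8 and stays open (odds ratio 1.82, 95% interval 0.461 to 5.26, p = 0.29 by Fisher's exact test without the genes that drew attention to it), and Fzd8 and Uchl1 lie on chromosomes 18 and 5. An effect of the genotype stays open as well.

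The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 0 genes, as many as or fewer than each of the 10 splits, and the highest other gave 1098, which points to a structure of the samples, as it set WT replicates 1 and 3 and KO replicate 3 against the rest. It gave 12 lists, a number reached by 3 splits with itself included, and the highest other gave 13. For the neighbourhood of Psip1 the real p was 0.019, reached by 1 split, itself, and the lowest other was 0.0486.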
